A study of Homo sapiens with 30 samples.

How the data were processed

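RNA from sorted human erythroblasts was sequenced in 30 libraries. The cells came from HUDEP2, an immortalised erythroid progenitor line (labelled HUDEP2 cas9), and from erythroid cultures of primary CD34-positive blood progenitors. Each culture was sorted into HbF-low cells (A cells, which hold little fetal hemoglobin) and HbF-high cells (F cells), and the series describes the sorted populations as matched for stage. The libraries fall into 14 groups. HUDEP2 gave A and F cells of 3 clones at day 7 (6 libraries). The CD34 cultures gave A and F cells of 2 donors at days 8, 11 and 14 without treatment (12 libraries, the time course), and A and F cells of 2 other donors at day 11 with no drug, hydroxyurea or pomalidomide (12 libraries, the drug series). The labels give no dose. Per the labels, RNA was taken from the sorted cells with a kit made for fixed tissue that includes a crosslink reversal, depleted of ribosomal and globin RNA, and made into stranded total RNA libraries that were sequenced in paired-end mode.

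The authors deposited a table per library. The submitters' processing notes name STAR, RSEM and genome build hg38, without versions or annotation. The deposited expected counts, RSEM's estimate of fragments per gene before any normalization, were summed per gene and rounded. The deposited TPM values (transcript abundances scaled by the authors over all entries of a table) were used only as an alternative for the gamma-globin share. The tables of the time course and the drug series hold 58721 gene identifiers, all of which are in GENCODE release 29 on GRCh38, from which symbols and coordinates were taken. The HUDEP2 tables hold 60554 identifiers, of which 56996 have a name in that release and 52179 the same version, so they were made with another release. The 92 spike-in entries were left out of all fits, as were XIST and Y-linked genes (516 in HUDEP2, 564 in the other tables).

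Gene counts were compared with edgeR 4.0.16 under R 4.3.3 (estimateDisp, glmQLFit with robust set, glmQLFTest), with TMM normalization and filterByExpr at a minimum count of 10. P-values were adjusted by Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with their standard error (SE), and a gene's adjusted p is from these edgeR fits unless another tool is named. HUDEP2 was fitted with sort alone, the time course with day and sort, and the drug series with treatment and sort. Within a day or treatment, and for changes in the F against A difference between days or treatments, a model of the 6 groups was used. The filter kept 14282 genes in HUDEP2, 12683 in the time course and 16457 in the drug series. Levels are TMM-normalized counts scaled to a common library size (CPM) with SD. A and F cells came from the same clone or donor. As a check of that pairing, deviations from the group means were correlated between libraries of the same clone or donor: 3 of 3 HUDEP2 pairs, 30 of 30 time course pairs and 24 of 30 drug series pairs of libraries exceeded 0.1. With 2 libraries per CD34 group the deviations mirror each other. Each value of the first donor therefore recurs in the second, and the CD34 counts include these repeats. All drug series pairs below 0.1 held a hydroxyurea A library, so the donor block there rests on the labels as given. The main tests had no clone or donor term, and the same fits with a clone or donor block were run beside them. Donors are few, so libraries pooled over days or treatments are not independent replicates, and the p-values describe these donors.

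The genes to be named were fixed before the data were examined. For each of the 7 main comparisons these were, among called genes with a mean of at least 5 CPM and the same sign in every matched pair, the 12 largest rises and the 12 largest falls, with free places going to genes that passed in the blocked fit. The other comparisons had 3 in each direction. Genes called in the same direction in all 3 pooled F against A fits, up to 4 members of each gene list with the smallest p, the globin genes, BGLT3, BCL11A, ZBTB7A, MYB, LIN28B, IGF2BP1, IGF2BP3 and HBS1L were also named. Genes known only by a clone name were left out.

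The 25 gene lists were fixed at the same time: globin locus genes, known gamma-globin regulators, heme and iron, late erythroid, early progenitor, S phase and DNA replication, G2 and mitosis, replication-dependent histones, p53 targets, ATF4 stress response, unfolded protein and heat shock, interferon response, glycolysis and hypoxia, cholesterol synthesis, nuclear and mitochondrially encoded oxidative phosphorylation, ribosomal proteins, autophagy and mitophagy, the cereblon complex and its reported substrates, the fetal erythroid or LIN28B axis, and markers of megakaryocytes, monocytes, neutrophils, mast cells and lymphocytes. Members were counted from the adjustment over all genes tested and, separately, adjusted over the list alone. Each list was tested with fry (limma 3.58.1), adjusted over the lists of a comparison. The fry p used here tests whether a list's genes move, on balance, in one direction, and its mixed p whether they change in either direction. Neither compares a list with other genes.

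The gamma-globin share is the percentage of HBG1 and HBG2 among the expected counts of HBB, HBD, HBG1, HBG2 and HBE1 in a library, with a 95% Wilson interval and exact permutation tests (scipy 1.17.1). Globin RNA had been depleted, and the globin genes (these with HBA1, HBA2, HBM, HBQ1 and HBZ) held 0.0018% to 0.0655% of a library's counts, so the share is a ratio among the remaining molecules. Where every library of a group held 0 counts, a fold is given as a bound against 3 counts per library. Intervals and bounds cover counting error only. HBG1 and HBG2, and HBA1 and HBA2, are near-identical copies, so the division of reads between them is uncertain, as are the HBG2 counts themselves, because its annotated span runs over other genes. Values were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plotted with matplotlib 3.10.9.

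Gene counts totalled 29580791 to 36281497 per library in HUDEP2, 2462841 to 6689855 in the time course and 32641150 to 45849125 in the drug series. The tests were also run on simulated data with 100 genes changed by each of 2 sizes. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery below that level was not measured. For the fits without a block, the simulated data held no other effect of clone, donor, day or treatment. The pooled F against A fits without a block recovered 80% (HUDEP2) and 94% (time course and drug series) of changes of 1 log2 unit, and 98% to 99% of changes of 2 log2 units. At 2 libraries against 2 these were 39% and 88% at day 14, and 53% and 94% in the drug series controls. False calls beside the 200 changed genes were 17 in HUDEP2 and 9 in each pooled CD34 fit, 11 at day 14 and 6 in the controls. With the block they were 31 in HUDEP2, 18 in the time course and 15 in the drug series, where 98%, 97% and 98% of changes of 1 log2 unit were recovered.

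The alternatives fixed before the data were examined were DESeq2 1.42.0, its size factors in edgeR (RLE), no count filter, library sizes without globin and mitochondrial genes, the clone or donor block, each library left out in turn, limma-voom for the F against A fits, and the mean of the within-day or within-treatment contrasts. For the gamma-globin share they were TPM and a share of HBG1, HBG2 and HBB alone. Alternatives chosen after seeing the data left out the libraries with the lowest depth or fewest genes, crossed the donor block for pomalidomide against hydroxyurea, and fitted both sets of CD34 libraries jointly.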

Results

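RNA-seq libraries of A cells (HbF-low) and F cells (HbF-high) were compared in 3 HUDEP2 clones at day 7 of differentiation and in untreated CD34-derived cultures of 2 donors at days 8, 11 and 14. Day 11 cultures of 2 other donors were grown without drug, with hydroxyurea or with pomalidomide. Hydroxyurea inhibits ribonucleotide reductase, pomalidomide binds the ubiquitin ligase substrate receptor cereblon, and both raise fetal hemoglobin. Each HUDEP2 group held 3 libraries and each CD34 group 2. Gene counts per library were 29580791 to 36281497 in HUDEP2, 2462841 to 6689855 in the time course and 32641150 to 45849125 in the drug series.

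The first question was how the fetal beta-like globin transcripts, HBG1 and HBG2, followed the sort. They made up 55.0% ± 6.0 (SD, n = 3) of beta-locus globin counts in HUDEP2 F cells and 0.711% ± 0.354 (SD, n = 3) in A cells. In the time course the share was 85.5% ± 6.68 (SD, n = 6) in F cells and 5.88% ± 6.91 (SD, n = 6) in A cells. In the drug series it was 84.8% ± 4.94 (SD, n = 6) in F cells and 2.7% ± 1.67 (SD, n = 6) in A cells. The A cell share averaged 13.7% ± 6.78 (SD, n = 2) at day 8, 3.3% ± 0.952 at day 11 and 0.601% ± 0.056 at day 14. In the A cells of the drug series it averaged 0.755% ± 0.549 without drug, 3.15% ± 0.31 with hydroxyurea and 4.19% ± 1.04 with pomalidomide. The F cells had 79.9% ± 2.13, 84.4% ± 2.59 and 90.3% ± 1.0 in the same order (SD, n = 2 each). The share was higher in F cells in every matched pair of both CD34 sets. The two-sided exact permutation p was 0.00216 in each (6 against 6), and the exact sign-flip p over the 6 pairs 0.0312, both the smallest possible. In HUDEP2 the exact permutation p was 0.1, the smallest that 3 against 3 allows. Globin RNA had been depleted, and the A libraries of the time course rest on 1 to 10 gamma-globin counts of 54 to 356 beta-locus counts. The day 14 A libraries held 1 and 2 of them, with 95% Wilson intervals of 0.113% to 3.54% and 0.154% to 2.02%, below those at day 8 (from 3.87%) and overlapping those at day 11 (from 1.03%). In the drug series the A libraries without drug had intervals reaching 1.85% and those with either drug started at 2.12%. With 2 libraries per group, no exact test of such differences could pass.

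**Figure D1:**
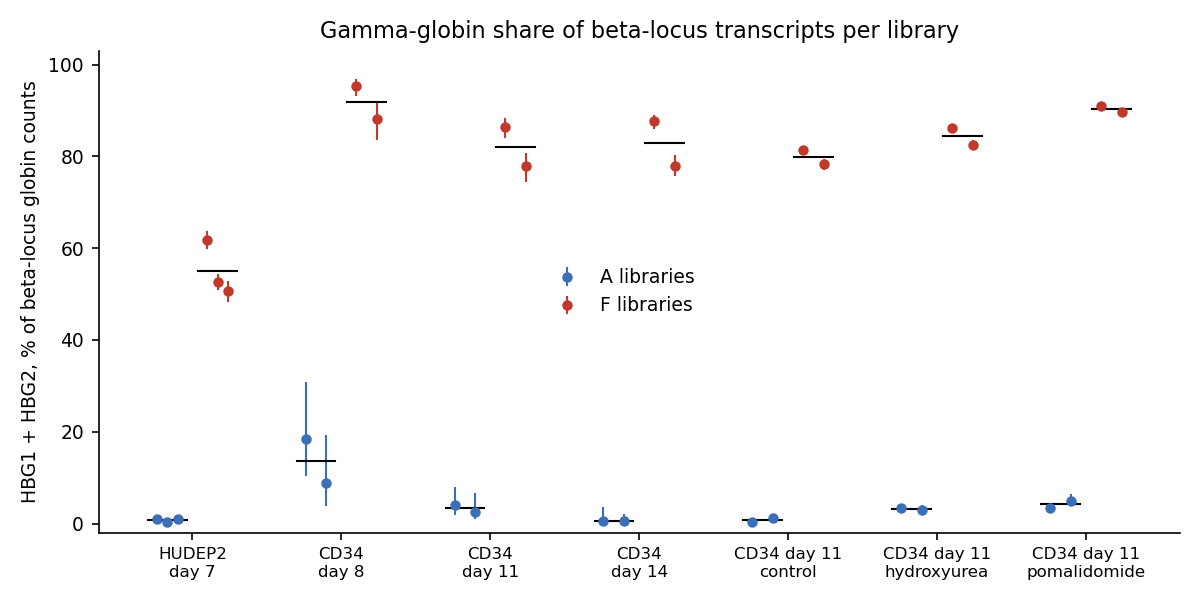
Gamma-globin share of beta-locus globin counts (%, HBG1 and HBG2) in each library, A cells in blue and F cells in red, with 95% Wilson intervals for counting error and a black bar at each group mean. Every F library lies above the A library of its pair, with means of 55.0% and 0.711% in HUDEP2.

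What distinguishes F cells from A cells of the same HUDEP2 clones, beyond the globin itself, came next. Here 4 of 14282 genes tested were called, all higher in F cells: HBG2, HBG1, BGLT3 and LIN28B. HBG2 (chromosome 11, 5253190 to 5505605) averaged 35.0 ± 9.95 CPM in F cells and 0.27 ± 0.0916 CPM in A cells (SD, n = 3), a log2 fold change of 6.99 ± 0.32 (SE, adjusted p = 1.83e-06). HBG1 (chromosome 11, 5248079 to 5249859) differed by 6.81 ± 0.64 (adjusted p = 0.00183). BGLT3, a noncoding RNA transcribed from between the gamma-globin and delta-globin genes (chromosome 11, 5244554 to 5245546), differed by 6.76 ± 0.40 (adjusted p = 5.61e-05), from 0.235 ± 0.186 to 25.7 ± 4.33 CPM. LIN28B (chromosome 6, 104936616 to 105083332), an RNA-binding protein of fetal hematopoiesis, averaged 1.93 ± 0.648 CPM in F cells and 0.15 ± 0.0555 CPM in A cells, a log2 fold change of 3.64 ± 0.49 (adjusted p = 0.0277).

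The established repressors of gamma-globin did not pass the test in HUDEP2. BCL11A differed by -0.29 on the log2 scale, ZBTB7A by 0.09 and MYB by 0.30, and the LIN28B partners IGF2BP1 and IGF2BP3 by 0.05 and 0.04. Of 10 globin locus genes tested, 3 were higher in F cells over all genes and 4 adjusted over the list alone (fry adjusted p = 0.00364, up; 0.0669 with the clone block). The fetal erythroid list held 1 called gene of 15, LIN28B, and its mixed fry adjusted p was 0.0149, with a median of -0.08 and a mean of 0.14. With clone as a block, 156 genes were called, 102 higher and 54 lower in F cells. On simulated data this fit made 31 false calls beside 98 and 99 of 100 changed genes of each size, so the genes called only with the block are less certain. Among them, adult HBB averaged 30.5 ± 5.69 CPM in F cells and 48.3 ± 18.0 CPM in A cells, a log2 change of -0.66 ± 0.25 (adjusted p = 1, and 0.00267 with the block). Other genes called only with the block included, among the rises, BEX1 (log2 1.04), the polyol enzyme SORD (0.94), the retinol acyltransferase LRAT (0.93) and the metallothionein MT2A (0.88). Among the falls were the desmosomal cadherin DSG2 (-1.05), the tyrosine kinase SYK (-1.01), the death receptor TNFRSF10B (-0.97) and the stress sensor ERN1 (-0.84).

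The same question in untreated primary cells, pooled over days 8, 11 and 14, gave 4 called genes of 12683, 3 higher and 1 lower in F cells (8 with the donor block). HBG2 was higher by 7.21 ± 0.46 (SE, n = 6, adjusted p = 3.81e-05), HBG1 by 6.55 ± 0.55 (adjusted p = 0.000931) and BGLT3 by 5.39 ± 0.49 (adjusted p = 0.000599). PLCL2, a phospholipase C-like protein without catalytic activity (chromosome 3, 16802651 to 17090594), was lower in F cells in 6 of 6 pairs, at 21.6 ± 19.6 CPM against 41.2 ± 39.1 CPM (log2 -0.87 ± 0.12, adjusted p = 0.0169). The receptor phosphatase PTPRF passed only with the donor block (log2 -1.42 ± 0.23, adjusted p = 0.0721, and 0.00625 with the block). HBB (-0.59 ± 0.14, adjusted p = 0.512), HBD (-0.71 ± 0.16, adjusted p = 0.386) and BCL11A (-0.22) were not called. Of the 25 lists only the globin genes passed fry (3 of 10 called, all higher, and 3 higher and 2 lower adjusted over the list alone, adjusted p = 8.8e-05, with a median of -0.01 and a mean of 1.80). This list holds HBG1, HBG2 and BGLT3, the sorted product and its locus. In each F against A fit its fry p therefore says little on the other globin genes.

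Within single days HBG2 was higher in F cells by 5.07 ± 0.53 at day 8 (SE, n = 2, adjusted p = 0.019), 8.63 ± 0.71 at day 11 (adjusted p = 0.00161) and 9.59 ± 0.69 at day 14 (adjusted p = 0.000426). It was the only call at days 8 and 11, each of which had 3 calls with the block. At day 14 there were 9 calls, 4 higher and 5 lower, and 72 with the block, 7 higher and 65 lower. BGLT3 averaged 24.5 ± 11.6 CPM in day 14 F cells and had no count in A cells, at least 23.7-fold higher. TCP11L2 (log2 -1.51 ± 0.23, adjusted p = 0.0467), TBCEL (-1.25 ± 0.16, adjusted p = 0.035) and the lipid phosphatase LPIN2 (-1.17 ± 0.17, adjusted p = 0.035) were lower in F cells at day 14. The change in the F against A difference between day 8 and day 14, tested as an interaction in edgeR, gave 0 genes, with 384 at an unadjusted p under 0.05 and 12 called by DESeq2.

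In the drug series, pooled over treatments, F cells again had more gamma-globin transcript. By list, early progenitor genes were higher on balance in F cells of this set, and late erythroid and ATF4 stress genes lower. Of 16457 genes 66 were called, 23 higher and 43 lower in F cells, and 199 with the donor block (93 and 106). BGLT3 was higher by 6.05 ± 0.37 (SE, n = 6, adjusted p = 2.9e-05), HBG1 by 7.04 ± 0.41 (adjusted p = 4.31e-05) and HBG2 by 7.70 ± 0.69 (adjusted p = 0.0045). With the globin pseudogene HBBP1 (1.01 ± 0.20, adjusted p = 0.0443), 4 of 12 globin genes were called (6 adjusted over the list alone, fry adjusted p = 0.00217, up). Outside that locus, the stem cell factor receptor KIT (chromosome 4, 54657918 to 54740715) averaged 41.1 ± 11.2 CPM in F cells and 24.2 ± 7.52 CPM in A cells (log2 0.78 ± 0.09, adjusted p = 0.00105). The chromatin remodeller CHD7 was at 50.1 ± 11.6 against 26.5 ± 7.76 CPM (0.93 ± 0.10, adjusted p = 0.000966). STAT5A, a transcription factor downstream of the erythropoietin receptor, was at 23.0 ± 5.14 against 12 ± 3.57 CPM (0.96 ± 0.15, adjusted p = 0.0229). Rises were also called for PLXND1 (0.93), APOE (0.83), AHCY (0.79), PRKCB (0.76) and MSN (0.62).

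Genes lower in F cells included the noncoding RNA MIAT at 18.6 ± 5.63 against 53.3 ± 10.6 CPM (log2 -1.56 ± 0.21, adjusted p = 0.0106). Complement C5 (-1.50 ± 0.21), TMCC2 (-1.39 ± 0.23), TCP11L2 (-1.43 ± 0.26) and the autophagy protein GABARAPL1 (-0.97 ± 0.18, adjusted p = 0.0329) were lower too. HMOX1, which degrades heme, averaged 2.69 ± 1.02 CPM in F cells and 8.14 ± 5.16 CPM in A cells (-1.43 ± 0.25, adjusted p = 0.0286). PLCL2 was lower here as well (-0.92 ± 0.17, adjusted p = 0.0336). The ATF4 stress response list was lower in F cells (fry adjusted p = 0.000569), with 3 of 29 members called lower and 0 higher (5 lower and 1 higher adjusted over the list alone). These were TRIB3 (-0.89 ± 0.12), DDIT3 (-0.64 ± 0.09) and CEBPG (-0.54 ± 0.10). Late erythroid genes were lower (2 of 40 called, 11 adjusted over the list alone, median -0.21, adjusted p = 0.0329). The called members were XPO7 (-0.83 ± 0.14) and the ubiquitin ligase TRIM58 (-0.57 ± 0.10), which act in erythroblast nuclear maturation. Early progenitor genes were higher on balance (1 of 17 called, KIT, and 6 adjusted over the list alone, adjusted p = 0.0329), with 11 positive estimates. The time course did not repeat this, with 6 of 18 early progenitor estimates positive and a median of -0.05 (fry adjusted p = 0.821). Another 3 lists passed only without the donor block, under which each had an adjusted p of 0.0616. Autophagy genes moved down (1 of 29 called, 5 lower adjusted over the list alone, adjusted p = 0.0369). So did G2 and mitosis (0 of 35 called, also adjusted over the list alone, adjusted p = 0.044). In the other sets the G2 and mitosis list did not pass and leaned up. There 31 of 35 estimates in the time course and 35 of 35 in HUDEP2 were positive. The p53 targets moved up (0 of 38 called, 1 higher adjusted over the list alone, adjusted p = 0.044). In edgeR 0 of 73 ribosomal protein genes were called and all 73 had a positive estimate (fry adjusted p = 0.0515). Of known gamma-globin regulators 0 of 38 were called over all genes, with 3 higher and 3 lower adjusted over the list alone (mixed adjusted p = 0.0131). MYB averaged 36.6 ± 6.53 CPM in F and 26.8 ± 2.99 CPM in A cells, higher in 6 of 6 pairs (0.44 ± 0.10, adjusted p = 0.0975, and 0.0446 with the block). IGF2BP3 averaged 0.751 ± 0.384 and 0.159 ± 0.158 CPM (2.58 ± 0.56, adjusted p = 0.078, and 0.047 with the block). BCL11A (-0.08), ZBTB7A (-0.08) and HBS1L (0.00) were not called. The spike-in share was 0.533% ± 0.0577 in A and 0.422% ± 0.0568 in F libraries of this set. The count of 66 rests on single libraries, falling to 10 without the hydroxyurea F library of the first donor, and to 38 as the mean of the within-treatment contrasts.

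Within single treatments, 2 genes were called without drug (3 with the block), 3 with hydroxyurea (4) and 3 with pomalidomide (35, of which 5 were higher and 30 lower). HBG1 and BGLT3 were called in each. TRIB3 was lower in hydroxyurea F cells (-1.34 ± 0.17, SE, n = 2, adjusted p = 0.0322). XPO7 was lower in pomalidomide F cells, at 190 ± 24.8 against 489 ± 120 CPM (-1.36 ± 0.18, adjusted p = 0.0317). HBG2 passed within treatments only with the block (adjusted p = 0.00457, 0.00592 and 0.00327, against 0.88, 1 and 0.147 without). Whether a drug altered the F against A difference was tested as an interaction in edgeR. It gave 0 genes for hydroxyurea (312 at an unadjusted p under 0.05, and 2 by DESeq2) and 0 for pomalidomide (366, and 1 by DESeq2).

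Across systems, HBG1, HBG2 and BGLT3 were called higher in F cells in all 3 pooled fits. With the globin genes and the other genes of the beta-globin locus left out, 58 of the 59 genes called in the drug series and tested in the time course had the same sign there. Of those tested in HUDEP2, also 59 but not all the same genes, 34 had the same sign in HUDEP2. Across genes, which are not independent replicates, the F against A fold changes of both CD34 sets correlated with a Spearman rho of 0.361 and a Pearson r of 0.361 (12589 genes, globin genes included). Without the globin genes the rho was 0.36 and r 0.243, and over genes with at least 5 CPM, globin genes included, the rho was 0.503. The rho was 0.11 between HUDEP2 and the drug series and 0.006 between HUDEP2 and the time course. A joint fit of both CD34 sets, chosen after the data were seen, called 0 of 16467 genes as differing in their F against A change between the sets. There were 445 at an unadjusted p under 0.05 and 0 with the block in edgeR, and DESeq2 was not run on this fit. Their mean gave 189 calls, 63 higher and 126 lower in F cells (552 with the block). Named after their values were seen, these included PLCL2 (-0.88 ± 0.11, adjusted p = 0.000101), KIT (0.64 ± 0.09, adjusted p = 0.000829), PRKCB (0.68 ± 0.10), PTPRF (-1.42 ± 0.21) and the AP-1 factor JUN (-1.16 ± 0.18, adjusted p = 0.00202).

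**Figure D2:**
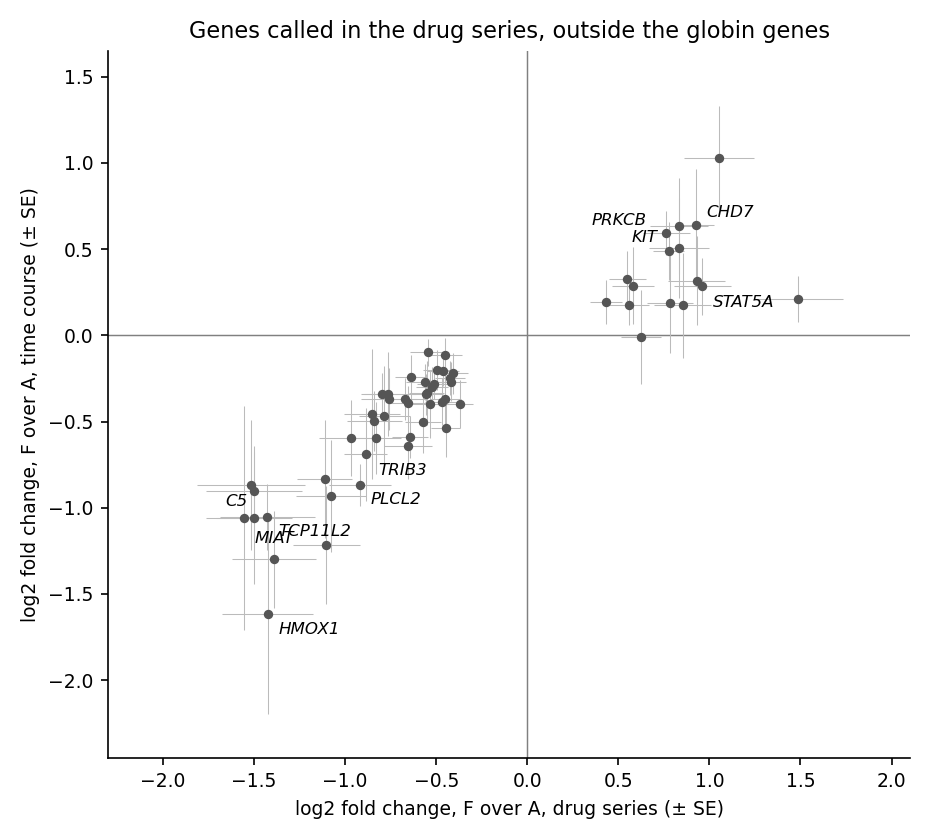
Log2 fold change (F over A, ± SE) in the drug series (x axis) and in the time course (y axis) of the 59 genes called in the drug series and tested in the time course, with the globin genes and the other genes of the beta-globin locus left out. In the time course 58 of the 59 have the same sign, with PLCL2 at -0.92 and -0.87.

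Maturation from day 8 to day 11 was followed over both sorts together, to see which programs the cultures passed through. Here 8132 of 12683 genes were called, 3900 higher and 4232 lower at day 11. Erythroid genes rose. HBM, an alpha-like globin, went from 1.4 ± 0.106 to 188 ± 13.6 CPM (log2 7.04 ± 0.25, SE, n = 4, adjusted p = 1.83e-10). ART4, which carries the Dombrock blood group, went from 1.56 ± 0.896 to 175 ± 17.4 CPM (6.75 ± 0.22), and HBB from 2.46 ± 1.14 to 22.4 ± 5.83 CPM (3.20 ± 0.19). The Lutheran blood group protein BCAM had no count at day 8 and 14.9 ± 6.28 CPM at day 11, at least 36.3-fold higher, and the pseudogene ABCC13 was at least 20.4-fold higher. IFIT1B rose from 0.0674 to 37.6 ± 14.6 CPM. Falls included MGST1 from 34.7 ± 1.75 to 0.187 ± 0.374 CPM (-7.17 ± 0.41) and the cytokine receptor CSF2RB from 22.7 ± 9.42 to 0.278 CPM (-6.21 ± 0.44). MYB, a progenitor transcription factor, fell from 254 ± 21.7 to 34.5 ± 6.15 CPM (-2.90 ± 0.14, adjusted p = 8.03e-10). GATA2 (-2.67), MYC (-2.51) and CDK6 (-2.36) fell too. BCL11A rose (1.16 ± 0.19, adjusted p = 0.000179), while HBG2 rose in edgeR (1.42 ± 0.43, adjusted p = 0.0113) and had the opposite sign in DESeq2 (-0.30, adjusted p = 0.859).

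By list, 39 of 40 late erythroid genes rose and 0 fell (median 2.39, fry adjusted p = 2.47e-08), with RHCE (4.53) and KEL (2.17) among them. So did 22 of 28 heme and iron genes, with 3 falling (adjusted p = 1.1e-07, ALAD 2.77), and 9 of 10 globin genes (adjusted p = 1.5e-07). Early progenitor genes fell (14 of 18, 1 rose, median -2.34, adjusted p = 1.71e-06). Division genes rose, with 33 of 35 in the G2 and mitosis list (34 adjusted over the list alone, adjusted p = 2.47e-08, NUSAP1 2.50) and 43 of 44 replication-dependent histones (adjusted p = 3.39e-07, HIST1H2BL 2.22). They included 19 of 36 S phase genes with 7 falling (adjusted p = 3.69e-05, RRM2 1.98). The ATF4 list rose (24 of 28, 1 fell, adjusted p = 2.47e-08), with CHAC1 at 4.28 ± 0.20 and ASNS at 2.68. Cholesterol synthesis fell (21 of 25, 1 rose, median -0.89, adjusted p = 1.71e-06, HMGCS1 -1.89 and DHCR7 -2.86). So did 17 of 25 unfolded protein and heat shock genes (5 rose, adjusted p = 7.32e-05, HSP90AB1 -2.36) and all 13 mitochondrially encoded subunits (median -1.65, adjusted p = 0.000282, MT-CO2 -1.22). Mitochondrial genes took 1.27% ± 0.332 of counts at day 8 and 0.57% ± 0.0327 at day 11, while the spike-in share was 0.361% ± 0.0341 and 1.41% ± 0.273. Autophagy genes rose (20 of 29, 1 fell, adjusted p = 3.71e-06, WIPI1 2.79 and OPTN 2.70). Other lists moved up on balance. These were gamma-globin regulators (19 rose and 11 fell of 37, adjusted p = 2.41e-05, SOX6 4.58), p53 targets (15 and 5 of 34, adjusted p = 0.000225) and cereblon genes (7 and 3 of 17, adjusted p = 8.24e-05, IKZF1 0.74). Fetal erythroid genes (8 and 2 of 12, adjusted p = 2.03e-05, GCNT2 2.84) and glycolysis (11 and 4 of 32, 11 and 3 adjusted over the list alone, adjusted p = 0.0177) did so too. Interferon genes were divided (14 and 10 of 32, adjusted p = 0.000144, up), with a median of 0.25 and a mean of -0.07. Nuclear oxidative phosphorylation (5 rose and 11 fell of 37, 4 and 10 adjusted over the list alone, adjusted p = 0.0849) and ribosomal proteins (20 and 4 of 73, 14 and 2 adjusted over the list alone, adjusted p = 0.235, mixed 0.00125) did not move one way. Among markers of other lineages, those of monocytes fell (3 of 4, 1 rose, adjusted p = 3.36e-05), with CD74 at least 4.16-fold lower and CD68 at -3.51. Mast cell genes fell (3 of 4, 1 rose, adjusted p = 0.0177, TPSB2 at least 3.13-fold lower), as did the lone lymphocyte gene tested, IGLL1, from 9.43 ± 1.83 to 0.0504 CPM. Neutrophil genes rose (2 of 3, adjusted p = 0.0048, LTF 2.02). Megakaryocyte genes were divided (2 rose and 3 fell of 6, adjusted p = 0.235, mixed 9.48e-07), with TUBB1 at 3.20 and ITGA2B at -4.52. Counts adjusted over the list alone were the same for every list at these days where none is given.

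From day 11 to day 14, 1127 genes were called, 506 higher and 621 lower at day 14. Genes of glycolysis and the hypoxia response were among those that fell. Hexokinase HK2 averaged 49.5 ± 4.04 CPM at day 11 and had no count at day 14, at least 60.1-fold lower. BNIP3 (chromosome 10, 131966455 to 131982013), a mitophagy receptor induced by hypoxia, fell from 690 ± 32.9 to 5.09 ± 2.03 CPM (log2 -7.05 ± 0.97, SE, n = 4, adjusted p = 0.0032). The glycolytic regulator PFKFB4 fell from 112 ± 15.4 to 0.583 CPM (-7.47 ± 1.08), and glucose-6-phosphate isomerase GPI from 159 ± 40.8 to 1.52 ± 0.696 CPM (-6.54 ± 0.31, adjusted p = 1.98e-07). The lactate exporter SLC16A3 fell as well (-6.79 ± 1.28). The metallothionein genes MT1G (134 ± 34.1 to 0.639 CPM, -7.60 ± 0.41) and MT1X (233 ± 71.3 to 3.16 CPM, -6.17 ± 0.34) were lower at day 14. Of 32 glycolysis and hypoxia genes 26 fell and 1 rose (27 and 1 adjusted over the list alone, fry adjusted p = 0.000811, median -3.35, and -3.24 with members at 0 counts set to their bound). The enzymes ALDOA (-3.44 ± 0.17), PGAM1 (-3.15 ± 0.20) and PFKL (-1.72 ± 0.13) were among them.

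Ribosomal protein genes fell together by smaller amounts at day 14 (69 of 73 called, 0 rose, 72 adjusted over the list alone, median -0.52, adjusted p = 0.00341), as RPL13A (-0.71 ± 0.10) and RPS18 (-0.70) show. MYB went from 34.5 ± 6.15 to 14.0 ± 3.35 CPM (-1.28 ± 0.16, adjusted p = 0.000278). Adult globins rose, HBB from 22.4 ± 5.83 to 43.1 ± 7.04 CPM (0.97 ± 0.16, adjusted p = 0.00165), HBA2 by 1.01 ± 0.23 and HBD by 0.74 ± 0.18. The globin list moved up (3 of 10 called, 4 adjusted over the list alone, adjusted p = 0.0298). IFIT1B went from 37.6 ± 14.6 to 225 ± 129 CPM (2.54 ± 0.23), and HMOX1 from 2.48 ± 1.73 to 17.2 ± 17.8 CPM (2.67 ± 0.64, adjusted p = 0.0223). Rises were also called for TMCC2 (2.40), TCP11L2 (1.98) and the monocarboxylate transporter SLC16A1 (1.74). Interferon genes (6 of 32 higher, 7 adjusted over the list alone, adjusted p = 0.0195, RSAD2 1.36) rose. So did autophagy genes (9 of 29 higher and 1 lower, 11 and 1 adjusted over the list alone, adjusted p = 0.0405, GABARAPL1 1.36, ATG14 1.16 and ULK1 0.94). Late erythroid genes had 9 rises and 1 fall of 40 (12 and 1 adjusted over the list alone, adjusted p = 0.0746). Another 3 lists passed only with the block. These were early progenitor genes (4 of 18 lower, 1 higher, 6 and 1 adjusted over the list alone, adjusted p = 0.0909, and 0.0304 with the block) and gamma-globin regulators (4 higher, 3 lower of 37, also adjusted over the list alone, adjusted p = 0.137, and 0.0403). The third was the unfolded protein list (3 higher, 1 lower of 25, 4 and 2 adjusted over the list alone, adjusted p = 0.211, and 0.0484). HBG2 (1.09, adjusted p = 0.119, and 0.0343 with the block) and HBG1 (0.68, adjusted p = 0.494, and 0.0245) also passed only with the block. The day 14 libraries had fewer genes detected than those of day 11 (15500 against 16100) and a spike-in share of 2.07% ± 0.485. Leaving out the shallowest A libraries of days 11 and 14 gave 352 calls, and leaving out the day 11 A library of the second donor 656.

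**Figure D3:**
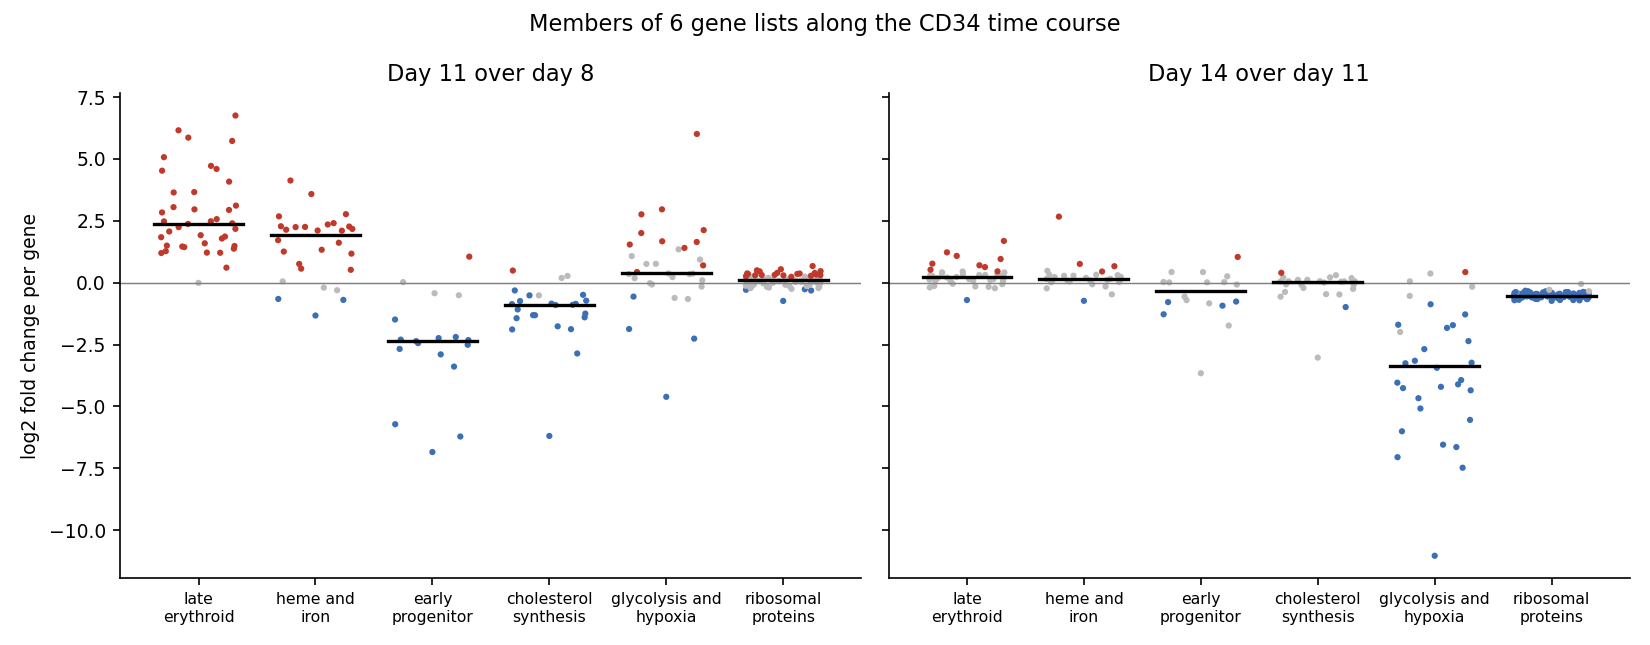
Log2 fold change of each tested member of 6 gene lists between days of the time course, with members called higher in red, called lower in blue and not called in grey, and a black bar at the list median. Glycolysis and hypoxia genes have a median of -3.35 from day 11 to day 14, where HK2's point is a fitted value against libraries with no count.

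Hydroxyurea against no drug, over both sorts, called 223 genes, 159 higher and 64 lower (433 with the donor block). Targets of p53 rose. CDKN1A (chromosome 6, 36676460 to 36687339), the cell cycle inhibitor p21, went from 2.56 ± 0.814 to 15 ± 3.39 CPM (log2 2.56 ± 0.26, SE, n = 4, adjusted p = 0.000336). The death receptor TNFRSF10B went from 3.75 ± 1.66 to 17.1 ± 2.74 CPM (2.26 ± 0.19, adjusted p = 0.000106). EDA2R (2.01 ± 0.17), PLXNB2 (1.85 ± 0.24) and TRIM22 (0.97) were called too. Over the list, 13 of 38 p53 targets rose and 0 fell (22 adjusted over the list alone, median 0.59, fry adjusted p = 7.58e-07), and 37 of 38 had a positive estimate. The ATF4 list fell (10 of 29 lower, 0 higher, 20 lower adjusted over the list alone, median -0.42, adjusted p = 7.58e-07). Of the serine synthesis enzymes, PHGDH fell from 7.05 ± 0.98 to 1.66 ± 0.807 CPM (-2.12 ± 0.24, adjusted p = 0.000672) and PSAT1 from 105 ± 6.54 to 50.6 ± 8.96 CPM (-1.06 ± 0.14). Other members called lower were TRIB3 (-1.11 ± 0.15), CHAC1 (-1.06 ± 0.23) and asparagine synthetase ASNS (-0.71 ± 0.09). The metallothionein genes MT1X (-1.43 ± 0.20) and MT1G (-1.36) and the BMP receptor BMPR2 (-1.27 ± 0.16) fell.

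Among globins, embryonic HBZ rose with hydroxyurea from 0.282 ± 0.26 to 1.72 ± 0.948 CPM (2.87 ± 0.63, adjusted p = 0.0366). It was the only call among 12 globin genes (2 adjusted over the list alone, fry adjusted p = 0.043, up). HBG2 (1.39 ± 0.73, adjusted p = 0.502), HBG1 (0.59 ± 0.43, adjusted p = 0.648) and BCL11A (-0.18) were not called. All cells had been sorted on fetal hemoglobin, so the contrasts of either drug compare cells within the A and F sorts. A change in the fraction of F cells in a culture would not show in them, and uncalled gamma-globin genes do not show that a drug left them unchanged. KIT rose (0.46 ± 0.10, adjusted p = 0.045, and 0.051 under RLE normalization), as did APOE (1.96 ± 0.20), PRX (1.71), UTRN (1.71) and CYFIP1 (1.53). The G2 and mitosis list moved down with 0 of 35 genes called, also adjusted over the list alone (adjusted p = 0.0163). S phase genes moved up with 0 of 36 called and 3 adjusted over the list alone (adjusted p = 0.0389, and 0.054 with the block), and monocyte genes with 0 of 4 called (adjusted p = 0.0385). The eosinophil granule gene PRG2 rose (1.10 ± 0.17, adjusted p = 0.0041) in a list that did not pass (1 of 8, adjusted p = 0.44), and 3 of 35 interferon genes rose (adjusted p = 0.1). The count fell to 94 without the hydroxyurea A library of the second donor.

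**Figure D4:**
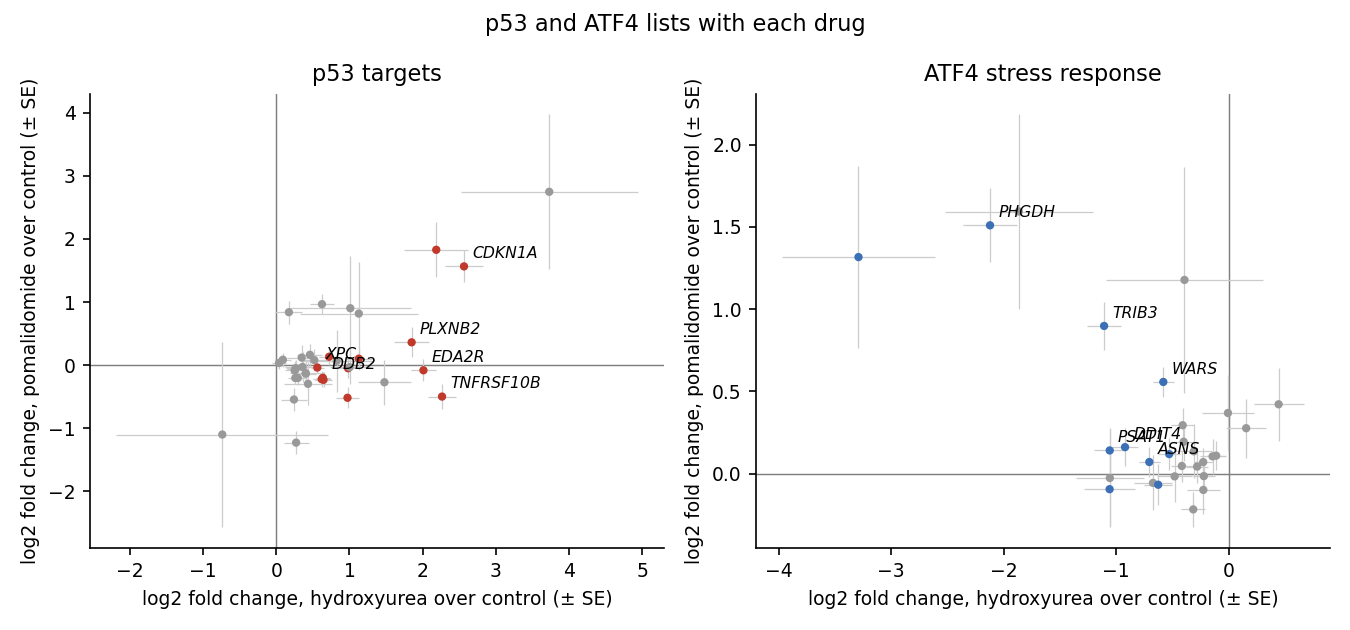
Log2 fold change (± SE) with hydroxyurea (x axis) and with pomalidomide (y axis), each against no drug, for the tested p53 targets and ATF4 response genes, coloured by their hydroxyurea call. With hydroxyurea 13 p53 targets were called higher and 10 ATF4 genes lower, and CDKN1A lies at 2.56 and 1.56.

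Pomalidomide against no drug called 1191 genes, 760 higher and 431 lower. Among the rises, CALB1, the calcium buffer calbindin (chromosome 8, 90058608 to 90095475), went from 0.163 ± 0.218 to 104 ± 44.5 CPM (log2 9.36 ± 0.49, SE, n = 4, adjusted p = 9.24e-07). CALB2, its relative calretinin, had no count without drug and 15.7 ± 3.62 CPM with it, at least 213-fold higher. PLLP went from 0.0588 ± 0.118 to 23.3 ± 7.0 CPM (8.62 ± 0.67). The protease CTSE rose from 2.7 ± 0.684 to 23.6 ± 13.4 CPM (3.10 ± 0.29), and CYFIP1 (4.12), the integrin ITGA5 (3.60 ± 0.30) and CASP4 (2.49 ± 0.20) rose. The lipid transporter ABCB4 fell from 16.9 ± 4.57 to 1.37 ± 0.554 CPM (-3.65 ± 0.29, adjusted p = 4.21e-06), as did AGPAT4 (-2.70 ± 0.24) and PRX (-2.43 ± 0.23). The alpha-like globin HBM fell from 81.2 ± 21.6 to 27.7 ± 4.7 CPM (-1.56 ± 0.18, adjusted p = 9.93e-05). Of 17 genes of cereblon and its reported substrates 2 rose and 0 fell (also adjusted over the list alone, adjusted p = 0.0125), the substrate transcripts ZNF692 (1.95 ± 0.13) and IKZF1 (0.87 ± 0.09).

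Late erythroid genes moved down with pomalidomide (4 of 40 lower, 0 higher, 16 lower adjusted over the list alone, median -0.30, adjusted p = 0.0091), with the water channel AQP1 (-1.31 ± 0.17), RHCE (-0.61) and CA2 (-0.52) among them. Heme and iron genes did so too (6 of 28 lower, 2 higher, 8 and 2 adjusted over the list alone, adjusted p = 0.0404, ALAD -0.68). Of 13 fetal erythroid genes 2 were lower and 1 higher (4 and 1 adjusted over the list alone, adjusted p = 0.0292, down), GCNT2 at -1.10 ± 0.11, ARID3A at -0.70 and IGF2BP3 at 2.59 ± 0.70. Early progenitor genes moved up (3 of 17, also adjusted over the list alone, adjusted p = 0.0175), KIT by 0.92 ± 0.10, MYC by 0.94 and GATA2 by 1.21 ± 0.30. The ATF4 list rose (3 of 29 higher, also adjusted over the list alone, adjusted p = 0.00106), PHGDH by 1.51 ± 0.22 and TRIB3 by 0.90 ± 0.14. Unfolded protein and heat shock genes (3 of 25, 7 adjusted over the list alone, adjusted p = 0.00106, HSPA1A 0.92) rose. Cholesterol synthesis genes rose as well (5 of 25, 12 higher and 1 lower adjusted over the list alone, adjusted p = 0.0143, SQLE 0.52). Interferon genes moved down (11 of 35 lower and 5 higher, 16 and 6 adjusted over the list alone, adjusted p = 0.0143, median -0.37 against a mean of 0.14), with EPSTI1 at -1.65 and HERC5 at 1.66. G2 and mitosis did so too (1 of 35 lower, also adjusted over the list alone, KIF20A -0.36, adjusted p = 0.0143). CDKN1A rose (1.56 ± 0.25, adjusted p = 0.0012) in a p53 list that moved both ways (4 higher and 1 lower of 38, 4 and 3 adjusted over the list alone, adjusted p = 0.903, mixed 1.59e-05). Glycolysis and hypoxia had 8 genes higher and 1 lower of 32 (11 and 5 adjusted over the list alone, adjusted p = 0.0666, and 0.0142 up with the block), with BHLHE40 at 1.52.

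Markers of other lineages were also higher with pomalidomide. Neutrophil genes rose (3 of 5, also adjusted over the list alone, adjusted p = 0.00106), LCN2 by 2.07 ± 0.29 and LTF by 1.87 ± 0.28. Megakaryocyte genes rose (2 of 17, also adjusted over the list alone, adjusted p = 0.0338), THBS1 by 1.40 and ITGA2B by 1.63. Monocyte genes moved up with 0 of 4 called (adjusted p = 0.0181). GATA2, also on the mast cell list, was the only call there (1 of 8, adjusted p = 0.215). HBG2 (2.13 ± 0.72, adjusted p = 0.135, and 0.0243 with the block) and HBG1 (1.27 ± 0.43, adjusted p = 0.117, and 0.0473) passed only with the donor block. Gamma-globin regulators had 3 rises of 38 (3 higher and 1 lower adjusted over the list alone, median -0.10 and mean 0.00, adjusted p = 0.155, and 0.0499 down with the block). BCL11A (-0.40, adjusted p = 0.139) and HBB (0.34) were not called, nor did the globin list pass (1 of 12 lower, 2 higher and 2 lower adjusted over the list alone, adjusted p = 0.528).

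**Figure D5:**
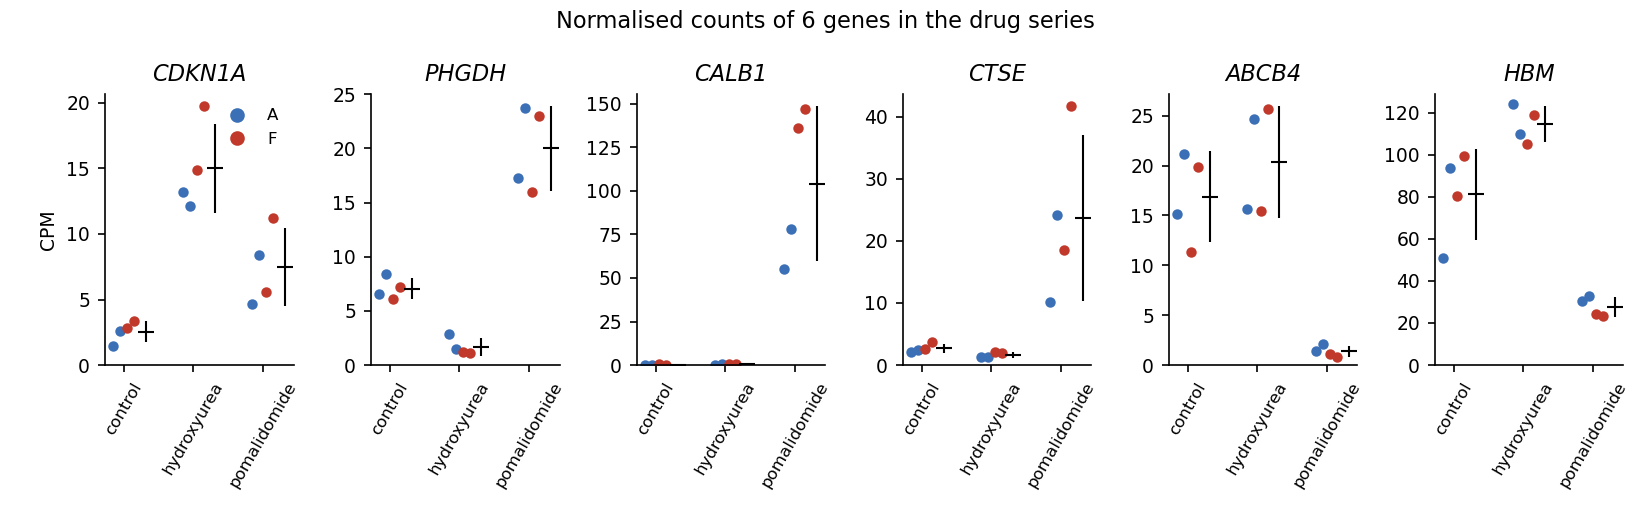
Level (CPM) of 6 genes in each drug series library, A cells in blue and F cells in red, without drug, with hydroxyurea and with pomalidomide, with bars at the mean ± SD (n = 4). CDKN1A was highest with hydroxyurea at 15 ± 3.39 CPM, and HBM averaged 27.7 CPM with pomalidomide against 81.2 CPM without drug.

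Set against each other, pomalidomide and hydroxyurea differed in 1726 genes, 880 higher and 846 lower with pomalidomide. CALB2 (8.66 ± 0.50), PLLP (8.06 ± 0.63) and CALB1 (8.04 ± 0.44) were higher with pomalidomide on the log2 scale. PRX (-4.14 ± 0.24, adjusted p = 2.03e-07), ABCB4 (-3.93 ± 0.30), HBZ (-5.04 ± 0.74, adjusted p = 0.00045) and HBM (-2.05 ± 0.19) were higher with hydroxyurea. HBG2 (0.74), HBG1 (0.68) and BGLT3 (0.70) were not called, which does not show that the drugs had equal effects on them. Of the genes called with both drugs against no drug, 50 were higher in both (7.34 for independent lists), among them CDKN1A, CYFIP1, UTRN and KIT, and 8 lower in both (1.68). PRX was among 19 genes higher with hydroxyurea and lower with pomalidomide (4.16), and PHGDH and TRIB3 among 12 with the opposite pattern (2.96). Both contrasts share their 4 control libraries, which the values for independent lists leave out of account. With separate controls for each drug (4 ways to split them), 16, 5, 14 and 5 shared genes moved the same way and 11, 10, 11 and 6 opposite ways, so an excess of same-direction calls was not seen in every split. The splits with 16 and 11, and with 5 and 10, gave each drug the controls of a single donor. There the donor difference entered both contrasts with opposite signs. The fold changes correlated across genes with r 0.37, against a mean of 0.503 in 30 simulations of unchanged groups with the same controls. Their covariance was 0.215 against 0.154, a difference of 0.061. The simulated libraries were drawn independently, with spreads from the fit without a donor term. Donor differences, which the real groups share, became independent noise there, so the real and simulated values are not like for like. In the data, with separate control libraries for each drug, r was 0.014 to 0.071 and the covariance 0.0144 to 0.0658. Where each drug had controls of both donors, r was 0.058 and 0.071 and the covariance 0.0579 and 0.0658.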

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

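The test of the spike-in share was chosen only after the data were seen. Of 16 groups of libraries examined for a library far from the others, 2 held one, where chance gives about 1 in 20. In the pomalidomide libraries of the drug series, the median level of the glycolysis and hypoxia list was 5.21 log2 CPM in the lowest library and up to 5.55 in the others, a gap of 0.941 of the whole range. Among the day 14 libraries of the time course, A cells of the first donor had 2462841 gene counts against up to 5600240 in the others, a gap of 0.971 of the range.

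The spike-in entries, which no comparison used, differed with the sort in the drug series. Their share was 0.533% ± 0.0577 (SD, n = 6) in A and 0.422% ± 0.0568 (SD, n = 6) in F libraries, a difference of 0.111 percentage points, higher in A cells in 6 of 6 pairs (two-sided exact sign-flip p = 0.0312, the smallest possible). In the other sets it was higher in A cells in 4 of 6 pairs (time course, exact sign-flip p = 0.125) and 2 of 3 pairs (HUDEP2, exact sign-flip p = 0.5, where 0.25 is the smallest possible). The labels do not say at which step the spike-ins were added.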

How the results depend on the processing

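The alternatives that left out libraries chosen for low depth or few genes, the crossed donor block and the joint CD34 fit were chosen only after the data were seen, and all others before. Of 10396 values of named genes under the alternatives, 6608 belonged to calls, of which 6026 stayed calls in the same direction, 581 lost the call and 1 reversed, and 111 uncalled values became calls. The reversed value was HBG2 from day 8 to day 11, at -0.2985 in DESeq2 (adjusted p = 0.859). Calls kept were 365 of 367 in DESeq2, 366 of 367 with RLE, 363 of 367 without the count filter, 367 of 367 with the clone or donor block, and 3878 of 4380 with a library left out. With limma-voom 33 of 37 were kept, and LIN28B in HUDEP2 (adjusted p = 0.152), HBG1 in the time course (0.179) and HBG2 in the drug series (0.119) were among those lost. The cause was not tested for these or for the counts that follow, except where named.

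Counts of genes past the threshold moved by over 1.5 times as follows. For F against A in HUDEP2 (4 genes) they were 9 in DESeq2, 59 without the filter, 156 with the replicate block and 2 with globin and mitochondrial genes left out. In the pooled time course (4) they were 15, 77, 8 and 2. At day 8 (1) they were 5, 24, 3 and 0, at day 11 (1) 3, 23, 3 and 0, and at day 14 (9) 70, 108, 72 and 5. In the pooled drug series (66) they were 433 in DESeq2, 562 without the filter, 199 with the block, 38 as the mean of within-treatment contrasts and 42 without the control A library of the first donor. Without drug (2) they were 11 in DESeq2, 141 without the filter and 1 without globin and mitochondrial genes. With hydroxyurea (3) they were 8 in DESeq2 and 55 without the filter, and with pomalidomide (3) 110, 172, and 35 with the block. Interactions (0 genes in edgeR) gave 12 in DESeq2 and 37 without the filter for day 14 against day 8, 2 and 90 for hydroxyurea, and 1 and 62 for pomalidomide. Hydroxyurea against control (223) gave 567 in DESeq2, 691 without the filter and 433 with the block. Day 14 against day 11 (1127) gave 352 without the day 14 A library of the first donor and the day 11 A library of the second. The fall without globin and mitochondrial genes follows from its construction, which removes globin genes from the test, except at day 14, where lower calls went from 5 to 3 (TCP11L2 at adjusted p = 0.0589). The correlation of F against A between CD34 sets was 0.503 over genes with at least 5 CPM, against 0.361.

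Leaving out each library in turn gave 3 to 6 genes in HUDEP2, 3 to 7 in the pooled time course (7 without the day 8 F library of the first donor), 7642 to 8328 for day 11 against day 8 and 656 to 1227 for day 14 against day 11. The latter was 656 and 731 without the day 11 A libraries of the second and first donor, 678 without the day 11 F library of the first, and 685 and 709 without the day 14 A libraries of the second and first. The pooled drug series gave 10 to 78: 10 without hydroxyurea F of the first donor, 13 without hydroxyurea A of the second, 14 and 16 without control F of the first and second, 33 without pomalidomide A of the first, 36 and 38 without pomalidomide F of the first and second, and 41 and 42 without control A of the second and first. Hydroxyurea gave 94 to 233: 94 and 98 without hydroxyurea A of the second and first donor, 105 and 123 without control F of the second and first, 121 and 127 without hydroxyurea F of the second and first, and 147 without control A of the second. Pomalidomide gave 766 (without control F of the second donor) to 1235, and pomalidomide against hydroxyurea 1074 and 1137 (without hydroxyurea A and F of the second donor) to 2064. Within groups, where the lone library left is assumed to vary like the other groups, day 8 gave 0 to 1 (0 without day 8 F of the first donor or any day 11 or 14 library). Day 11 gave 0 (without either day 11 A library) to 2 (without either day 11 F or day 8 A library). Day 14 gave 1 (without day 14 A of the first donor or either day 14 F library) to 7, with 2 without day 14 A of the second donor or either day 11 A, 3 without either day 11 F and 5 without day 8 F of the second donor. Control gave 1 (without control A of the first donor, or either control F, hydroxyurea A or pomalidomide A library) to 6 (without control A of the second donor). Hydroxyurea gave 0 (without hydroxyurea A of the first donor) to 3, with 1 without hydroxyurea A of the second donor or either control F or pomalidomide A library. Pomalidomide gave 0 (without pomalidomide A of the first donor) to 17 (without pomalidomide F of the first), with 10 without pomalidomide A of the second and 1 without either control F or hydroxyurea A library. The hydroxyurea interaction gave 0 to 1 (without control A of the second donor) and the others 0.

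The replicate block moved the calls given in the report and, among 175 list tests (8 with no fry value), left 54 past the threshold as before, 49 of them shared. Mixed calls, for change in either direction, went from 84 to 101, with 17 changed. In the drug series the hydroxyurea A libraries deviated opposite to control A (r -0.098), pomalidomide A (-0.185) and pomalidomide F (-0.234) of their labelled donor. With control F (0.38) and hydroxyurea F (0.269) they shared the direction. All other pairs of one donor had r of 0.248 or more. Crossing the block exchanged the donor labels of the hydroxyurea A libraries. It gave 2400 genes for pomalidomide against hydroxyurea, against 2274 with the labelled block. No other blocked drug series result was run with exchanged labels, so those rest on the labels as given. The difference in gamma-globin share stayed between 50.9 and 56.5 percentage points in HUDEP2, 77.7 and 82.2 in the time course and 80.9 and 83.4 in the drug series with a library left out, and was 55.6, 78.0 and 80.6 from TPM. Simulated changes of 1 log2 unit were recovered in 39% at day 14 and 53% in drug series controls (2 against 2), and 94% in both pooled CD34 fits. These values hold for genes with at least 5 CPM and data without a donor effect. Depth was not isolated.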

Other observations

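The tests of maturation, of other lineages in the A sort, of a one-way course over the days and of megakaryocytes were chosen only after the results they bear on were seen, as was the comparison of A and F library totals. The genes of the first paragraphs were also chosen after their values were seen.

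Beyond the genes in the report, the mean of both CD34 sets in the joint fit had lower levels in F cells of SEL1L (-0.39), a component of endoplasmic reticulum-associated degradation, DDIT3 (-0.43), BPGM (-0.44), which makes an allosteric ligand of hemoglobin, and the insulin receptor substrate IRS2 (-0.51). ATG14 (-0.52), the urea transporter SLC14A1 (-0.61), IFIT1B (-1.27) and TMCC2 (-1.33) were lower as well, and GATA5 (1.05) was higher. These are log2 fold changes with an adjusted p under 0.05 in edgeR. Embryonic HBE1 averaged 0.961 ± 0.728 CPM (SD, n = 2) in pomalidomide F cells, with a single count in the A cells.

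PRG2, which codes for a granule protein of eosinophils, averaged 35.0 ± 6.02 CPM without drug, 74.9 ± 17 with hydroxyurea and 25.2 ± 3.25 with pomalidomide (SD, n = 4). THBS1 was at 7.87 ± 3.18, 3.8 ± 1.05 and 20.7 ± 5.08 CPM, and TUBB1 at 37.1 ± 4.19, 46.9 ± 4.81 and 37.5 ± 5.0 CPM.

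Unequal depth as a source of the genes lower in F than in A cells of the drug series is argued against by equal totals (41.2 M counts on average in both sorts). After thinning to 32.6 M, 76.7% of the calls were kept, short of the bound set beforehand. All 60 kept their sign, with a median size of 0.75 against 0.76 log2 units. Thinning draws from the same counts, so kept signs and sizes say little on depth. Cells of another lineage in the A sort stay open: 0 of 4 other-lineage lists tested moved down, with 17, 4, 5 and 8 genes, but the lymphocyte list had 0 genes tested and the mast cell list changed in both directions (mixed adjusted p = 0.0154). A candidate explanation is that A cells were further along maturation at the same day: for 91.5% of the genes (54 of 59) the estimate from day 11 to day 14, in other donors, had the sign opposite to F against A, against 60.9% of all genes, and of the 31 called between these days 29 were opposite. The series describes the sort as matched for stage, and a program of the sorted cells that uses the same genes stays open.

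Glycolysis and hypoxia genes lower at day 14 could follow from a shallow library, from maturation or from the day 11 harvest. Without the shallowest day 14 library 88.5% of the falling members (23 of 26) were still called. The list median was 7.32 ± 0.13 log2 CPM at day 11, 0.94 above day 8 (6.38 ± 0.83) and 3.55 above day 14 (3.77 ± 0.24). The rise from day 8 was 0.13 in the first and 1.74 in the second donor, so maturation along the culture cannot be told apart from the other explanations with 2 donors. Untreated day 11 cells of the drug series, a set filtered and normalized on its own, stood at 5.14 ± 0.33. They were nearer to day 14 (1.37 above it) than to day 11 (2.18 below it) of the time course. This was the outcome set beforehand for a culture condition particular to that day 11 harvest. In the first donor, however, the day 8 libraries already stood at 7.08 and 7.12, against 7.27 and 7.2 at day 11. A high level was thus not particular to day 11 in that donor. A condition of the day 11 or the day 14 harvest and a difference between donors stay open.

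Neutrophil and megakaryocyte genes higher with pomalidomide could come from other cells or from erythroid cells at an earlier stage. Of MPO, ELANE, AZU1, PRTN3 and CTSG, abundant in neutrophil precursors, 0 of 5 were called higher, but ELANE, PRTN3 and CTSG, with 1, 0 and 3 counts over the drug series, had too few to be tested. MPO was at 0.151 CPM without drug and 0.174 with it, while LCN2 went from 1.0 to 4.14 and LTF from 1.57 to 5.36 CPM. Of 5 abundant megakaryocyte genes 1 was called higher, ITGA2B, while PF4 went from 0.356 to 0.618 and PPBP from 1.06 to 1.53 CPM without a call. An earlier stage cannot be told apart from a drug effect. In the time course 2 of 3 neutrophil genes tested rose from day 8 to day 11 and 0 fell (fry adjusted p = 0.0048). An earlier stage would make such genes lower with pomalidomide, not higher. ITGA2B fell between these days, so its rise with pomalidomide has the direction of an earlier stage. Of the genes called with pomalidomide 72.6% had a sign opposite to the estimate from day 8 to day 11, against 65.4% of all genes. Of the 818 called between these days 635 were opposite. Hydroxyurea, set against the same control libraries, also gave 72.6% (146 of 201), against 58.6% of all genes. The share was thus not particular to pomalidomide.

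Other splits of the same libraries were used to ask whether chance can be excluded. For each day and drug comparison only the real split, 1 of 35, gave as many genes. It gave 8132 against 0 in the highest other split for day 11 against day 8, and 1127 against 73 for day 14 against day 11. For hydroxyurea it gave 223 against 17, for pomalidomide 1191 against 129, and for pomalidomide against hydroxyurea 1726 against 1. The splits with 73, 17 and 129 genes followed the donors. The 35 splits of each comparison leave the 2 donors out of account, so chance was not excluded at the level of donors. Among the 8 that part every pair of libraries of one donor and sort, only the real one gave as many genes, with 0 in the highest other, and 8 splits are too few to give a share under 0.05. For F against A in HUDEP2, 2 of 10 splits gave 4 or more genes, with 28 in the highest other, and 10 splits are too few to give a share under 0.05. In the time course 8 of 100 splits gave 4 or more genes (1534 in the highest other) and in the drug series 5 of 100 gave 66 or more (2915 in the highest other), so chance was not excluded by these. Splits with so many calls point to a structure of the samples beyond the sort. The highest put 4 (time course) and 5 (drug series) of the 6 libraries of one donor on one side. A placement of 4 of 6 is common among random splits, and whether the donors gave these calls was not tested. Among the 32 splits that part every pair of A and F libraries, only the real one gave as many genes in either set, with 1 gene in the highest other. In the drug series 60 of these 66 genes lie outside the globin genes and their locus. Its 6 pairs come from 2 donors, and the paired splits treat pairs of one donor as independent. Chance was therefore not excluded at the level of donors. In the time course 3 of the 4 genes were HBG1, HBG2 and BGLT3, the sorted product and its locus, so the paired splits say little on other genes there. The other paired splits put A cells and F cells on each side.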
